A study of Homo sapiens with 10 samples.

How the data were processed

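The data are mRNA sequencing profiles of LS180, an established human colorectal cancer line, carrying CRISPR interference. In that method a catalytically inactive Cas9 is directed by a guide RNA to a gene's promoter and represses its transcription. There were 5 stable lines: 2 with non-targeting guides (NTC1 and NTC2) and 3 with guides against RNASE1 (sg1, sg2 and sg3). Each line had 2 libraries, lettered A and B, which gave 10 libraries. Per the labels' protocols the cells received no drug, RNA was extracted on columns, polyadenylated RNA was captured with oligo(dT) beads, and cDNA was made with random primers by a procedure that does not mark strand. Nothing in the labels says whether A and B came from separate cultures, so p-values measure the spread between these samples, which may be technical in part.

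The authors deposited 1 table of expected counts per gene, which RSEM estimated per the name of the table and which need not be whole numbers. Per the submitters' processing notes, the genome build was hg38 and CASAVA 1.8.2, TopHat2 2.0.8 and FastQC 0.11.2 were used; their roles and the annotation release are not given in the sources used here. RSEM divides reads that fit several genes among them, so overlapping genes, paralogs and read-through genes have uncertain counts. The table held 58870 genes, and 7.12% of its values were not whole. Counts were rounded to whole numbers before testing, which moved no value by more than 0.5. Gene positions come from GENCODE release 29 on GRCh38; 58597 of the deposited identifiers matched it once version numbers were removed. The table holds no spike-in controls, and all values are relative to the library total, so a uniform change in RNA per cell cannot be measured.

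Library totals ranged from 39026564 to 45050950 counts, and 15450 to 15830 genes per library had at least 10 counts. Between the 2 libraries of a line, counts differed by 8.27 to 17.8 times the sampling variance, so no pair looked like a repeat of 1 library. Floors cover counting error only, and intervals cover counting error and the spread between lines or libraries as fitted.

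For the comparison of arms, counts of A and B were summed per line, and 3 guide lines were tested against 2 NTC lines with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with its default estimate, TMM normalization, filterByExpr, two-sided). Each guide line was compared with the mean of NTC1 and NTC2 in a single fit of all 10 libraries with 5 line means, and the same fit gave NTC2 against NTC1 and an F test of a difference among the guide lines. Adjusted p is the Benjamini-Hochberg value over all tested genes with a threshold of 0.05, unless another family is named. Standard errors were taken from the fold change and its F statistic, and 95% intervals from the corresponding t quantile. CPM is the usual depth-scaled count of edgeR, here after TMM scaling. Mean ± SD is over lines in the comparison of arms and over the libraries of a line elsewhere.

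A total of 33 gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, beside camera with an estimated correlation and the rotation test fry, read for a shift in 1 direction unless the text names its test for either direction. Lists with fewer than 5 measured members were left out, and adjusted p for lists is over the lists of a comparison.

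The tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The 500 kb window around RNASE1, the contrasts between pairs of guide lines and the correlations between guides were not part of that plan. The rule took RNASE1; then, per direction in the comparison of arms, up to 12 genes past the threshold with all guide libraries on one side of all NTC libraries and at least 1 CPM, filled up from genes changed in 1 direction by all 3 guides. It also took up to 5 genes per direction for each guide and for NTC2 against NTC1, the 5 genes with the smallest p for the difference among guides, up to 4 members of each list past its threshold, and any locus neighbour past the gene test. Only RNASE1 met the first part, so other genes are said to have been chosen after their values were seen. Examples from a list without a call were taken from its 3 most abundant members, a rule set after the data had been seen that does not use the fold change. Members past the threshold over a list alone, other than those the rule takes, were named after their values were seen.

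The letters act as a batch. The first principal component, with 18.2% of the variance, ran from -22.0 to -13.2 in the A libraries and from 8.38 to 19.7 in the B libraries. Deviations from line means were correlated between all 10 pairs of same-lettered libraries over 9527 genes at 10 CPM or more (r from 0.483 to 0.779), and between 8 of 10 pairs by over 0.1 over all 16411 genes tested (r from 0.0647 to 0.189). The pairing is read from these values and from the shared letters, not from a statement in the labels. Values with the letter as a block, and within each letter, stand beside a result where they change it.

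The count test was checked on simulated data drawn from the means, dispersions and library sizes of these libraries, with 200 changed genes in each of 5 simulations. In the comparison of arms over 17070 genes, 76.7% of genes at 1 CPM or more that were changed by 1.25-fold were recovered, 90.9% at 1.5-fold, 97.8% at 2-fold and 99.5% at 4-fold, and 5.96% of calls were false. For sg1 against NTC over 16121 genes the shares were 10.1%, 65.5%, 86.6% and 97.4%, and 11.8% of calls were false. Over all simulated genes the shares were 58%, 71.6%, 73.6% and 92% for the arms and 8%, 51.6%, 70% and 81.6% for sg1. These simulations treat genes as independent. The adjusted threshold is easier to pass with 200 changed genes than with the 4 genes called between the arms. The shares therefore overstate recovery where few genes change.

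Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, the letter as a block, all 10 libraries with an arm term or line means, voom with duplicateCorrelation, each letter alone, each control line alone, and leaving out each library and each line. A correction for transcript GC content, the newer quasi-likelihood estimate in edgeR, line means with a block, and further settings for the gene lists were added after seeing the data.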

Results

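LS180 cells, a human colorectal cancer line, were profiled by mRNA sequencing after CRISPR interference against RNASE1, which encodes a secreted ribonuclease of the RNase A superfamily. The series concerns a role of this enzyme inside the cell in restraining gene expression. The data comprised 4 libraries from 2 lines with non-targeting guides (NTC1, NTC2) and 6 libraries from 3 lines with RNASE1 guides (sg1, sg2, sg3), at 39026564 to 45050950 expected counts per library. Each line had libraries A and B. Nuclear genes for ribosomal proteins took 7.07% to 8.01% of counts and the mitochondrial genome 1.17% to 1.54%.

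RNASE1 was lower in each of the 6 guide libraries than in each of the 4 NTC libraries. Its level was 20.6 ± 0.58 CPM (SD, n = 2 lines) in the NTC lines and 2.12 ± 1.253 CPM (SD, n = 3 lines) in the guide lines. The log2 fold change was -3.26 (SE 0.23), which left 10.4% of the NTC level (95% interval 7.35% to 14.7%; edgeR quasi-likelihood test, adjusted p = 8.37e-05). The gene (ENSG00000129538) lies on chromosome 14 from 20801228 to 20803278 on the minus strand of GRCh38. The NTC libraries held 16.3 and 23.7 CPM in NTC1 and 19.3 and 22.9 CPM in NTC2, for letters A and B in that order. The libraries of sg1 held 1.02 and 1.37 CPM, those of sg2 3.35 and 3.76 CPM, and those of sg3 1.66 and 1.58 CPM. With A libraries alone the log2 fold change was -3.13, and with B libraries alone it was -3.37.

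**Figure D1:**
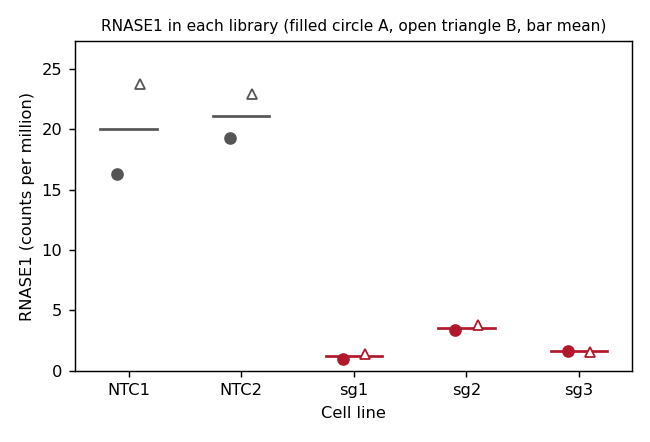
RNASE1 in CPM (vertical axis) in each library of the 5 lines (horizontal axis), with filled circles for A, open triangles for B and bars for the mean of a line. The 6 guide libraries lie between 1.02 and 3.76 CPM and the 4 NTC libraries between 16.3 and 23.7 CPM.

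Beyond RNASE1, the comparison of arms found few changed genes. Of 17335 genes tested, 3 were higher and 1 was lower in the guide lines, the lower one being RNASE1 itself. SOD3, which encodes extracellular superoxide dismutase, was higher by 0.26 on the log2 scale (SE 0.03, adjusted p = 0.0121), at 62.9 ± 1.66 CPM (SD, n = 2 lines) in NTC lines and 75.1 ± 1.19 CPM (SD, n = 3 lines) in guide lines. TNS4, which encodes a tensin family protein of focal adhesions, was higher by 0.21 (SE 0.03, adjusted p = 0.0147), from 614 ± 12.3 to 711 ± 11.6 CPM. SOD3 (ENSG00000109610) lies on chromosome 4 from 24789912 to 24800842, and TNS4 (ENSG00000131746) on chromosome 17 from 40475828 to 40501597. Both were named after their values had been seen, because their guide and NTC libraries overlapped across letters. Within letter A and within letter B, each of the 3 guide lines exceeded both NTC lines for both genes. For SOD3 the guide libraries started at 74.4 CPM against at most 71.1 CPM in NTC for A, and at 70.7 CPM against at most 57.4 CPM for B. With the letter as a block over all 10 libraries 2 genes passed, RNASE1 and TNS4 (log2 fold change 0.21, adjusted p = 0.0149), and SOD3 missed the threshold (0.26, adjusted p = 0.0852). Line means with the block gave 9 genes, and 3 with a correction for GC content as well. Both sets held AC000120.3 (fitted at 4.53 and 4.55), named after its values had been seen. In the same blocked fit it differed by 8.85 (SE 1.07) between NTC2 and NTC1. Its call therefore does not separate a difference between arms from one between the control lines. With the GC correction on the summed lines SOD3 stood at 0.21 and TNS4 at 0.19 (both edgeR adjusted p = 0.0374). With line means, the block and the GC correction SOD3 stood at 0.21 (adjusted p = 0.147) and TNS4 at 0.18 (adjusted p = 0.0454). A libraries alone gave 11 genes and B libraries alone 3. SOD3 was at 0.14 with A libraries alone (adjusted p = 0.382) and 0.38 with B libraries alone (adjusted p = 0.0297), and TNS4 missed the threshold in both (0.19, adjusted p = 0.0512, and 0.23, adjusted p = 0.456). Leaving out any single library except sg1 B ended the calls of both genes (0.18 to 0.33 for SOD3, 0.15 to 0.28 for TNS4), as did leaving out line NTC2 (0.23 and 0.19). Leaving out line sg2 (0.21) or line sg3 (0.20) ended the call of TNS4. Leaving out a single library unbalances the letters in the summed lines, so those values may mix letter with arm.

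The remaining gene past the threshold, AC010487.3 (ENSG00000283088, chromosome 19 from 52880663 to 52962768), was also named after its values had been seen. It had 0 counts in the 4 NTC libraries and 146 counts over the 6 guide libraries, with 0 to 58 in each. With a floor of 3 counts over the NTC group its allotted counts were at least 33.4-fold higher, a bound for counting error only. Its annotation overlaps ZNF816 and ZNF321P on the same strand, at log2 fold changes of -0.04 (SE 0.06) and 0.02 (SE 0.11), so its counts depend on how reads were divided among these genes. Another overlapping gene on that strand, the read-through gene ZNF816-ZNF321P (chromosome 19 from 52928475 to 52962823), also had 0 counts in the 4 NTC libraries. It had 76 counts over the 6 guide libraries, with 0 to 33 in each, at least 17.4-fold higher by the same floor (edgeR adjusted p = 0.109, DESeq2 adjusted p = 0.00628). In sg3 it had 0 counts in A and 33 in B, where AC010487.3 had 31 and 9. In sg1 it had 3 and 7 against 58 and 0, and in sg2 18 and 15 against 22 and 26. The 2 genes may share reads, so they are not separate support for a rise. With the letter as a block the adjusted p of AC010487.3 was 0.123, and the call of AC010487.3 ended when NTC2 B (adjusted p = 0.0780), sg1 A (0.654) or sg3 A (0.156) was left out.

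The precision of the comparison bounds what other genes could have done. Among 13036 genes at 1 CPM or more, the 95% interval of the fold change lay within 1.5-fold in either direction for 12638 (96.9%). Over all 17335 tested genes it did so for 12810 (73.9%). The median standard error of the genes at 1 CPM or more was 0.04 on the log2 scale, and the SD of their log2 fold changes was 0.10. At an unadjusted p under 0.05 there were 1195 of them, against 652 for uniform p-values. Across 9523 genes at 10 CPM or more, the fold change also rose with transcript GC content (Spearman's rho 0.500). GC bias of libraries may account for that trend, and its share in the excess was not tested. DESeq2 called 55 genes in the same comparison, 45 higher and 10 lower, and these included the 4 genes above. With no filter on low counts edgeR called 238.

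**Figure D2:**
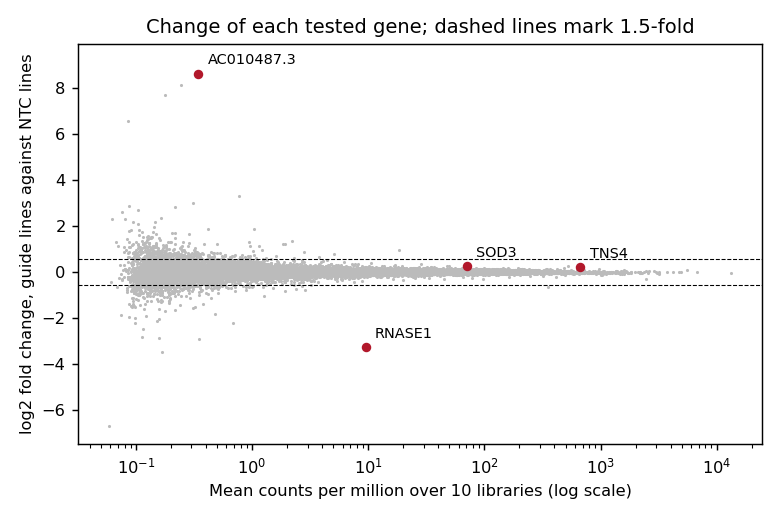
Log2 fold change of guide lines against NTC lines (vertical axis) for each tested gene by its mean CPM over 10 libraries (horizontal log axis), with dashed lines at 1.5-fold and the 4 genes past the threshold in red. RNASE1 lies at -3.26, SOD3 at 0.26 and TNS4 at 0.21; the fitted value of AC010487.3 is not a bound because its NTC counts were 0.

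Gene lists covered immune, growth, stress, metabolic and differentiation programmes. Apart from RNASE1, 753 listed genes were measured, and 0 of them passed the edgeR test over all genes. At an unadjusted p under 0.05 there were 81, and DESeq2 called 2, SMOC2 and ITGB4. The fold change interval lay within 1.5-fold for 685 of them (91.0%). Of 33 lists 1 passed camera, the goblet and secretory cell markers, and its adjusted p was 0.943 with an estimated correlation. With the letter as a block 3 passed: the goblet markers, the mitochondrial-genome mRNAs (median -0.09, adjusted p = 0.0368) and the ribosomal proteins (-0.02, adjusted p = 0.0235), with adjusted p of 0.612, 0.897 and 0.897 with an estimated correlation. With A libraries alone 5 passed. These were the goblet markers, the ribosomal proteins (-0.07), the mitochondrial-genome mRNAs (-0.21), oxidative phosphorylation (-0.06) and the TNF and NF-kB targets (0.09). With B libraries alone 2 passed, the goblet markers and the ribosomal proteins, the latter in the other direction (0.04). With an estimated correlation the adjusted p of these lists was 0.803 to 0.873 for A and 0.952 for B.

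The goblet and secretory markers, genes of the mucus-producing cells of the gut, were lower as a list in the guide lines. The median log2 fold change of 28 measured members was -0.11, with 22 negative and 6 positive (camera adjusted p = 0.000999). The call was lost with an estimated correlation and with fry's test for a shift in 1 direction (adjusted p = 0.662). Over all genes 0 members passed edgeR and 0 passed DESeq2, with 14 at an unadjusted edgeR p under 0.05, and adjusted over the list alone 12 fell and 1, SPINK1, rose. The gel-forming mucins MUC2, MUC5AC and MUC5B had log2 fold changes of -0.30 (SE 0.06), -0.27 (SE 0.06) and -0.15 (SE 0.04), and the mucus protein FCGBP one of -0.20 (SE 0.04). MUC2 passed over all genes in 4 of 28 alternatives: with no filter, without line NTC1 (-0.39, adjusted p = 0.0321), without line sg3 (-0.36, adjusted p = 0.0281) and without sg3 B (-0.41, adjusted p = 0.0166). With a library or line left out, MUC2 ranged from -0.49 (without NTC2 A) to -0.08 (without NTC2 B), MUC5AC from -0.40 (without sg1 B) to -0.16 (without sg1 A) and MUC5B from -0.24 (without NTC2 A) to -0.06 (without NTC2 B). FCGBP turned positive without NTC1 B (0.05) and without NTC2 B (0.06). Leaving out a single library unbalances the letters in the summed lines, so these values mix letter with arm. Within each letter, every guide library lay below both NTC libraries for MUC2 and FCGBP. This did not hold for MUC5AC, because of sg1 B, or for MUC5B, because of sg2 A. OLFM4, a marker of intestinal stem cells that is in none of the lists, was at -0.65 (SE 0.13, adjusted p = 0.197) and REG1A, which encodes a secreted lectin, at -2.23 (SE 0.57, adjusted p = 0.296). With line means and the letter as a block both passed (-0.58 and -2.94, adjusted p = 0.0454), and with the GC correction as well both missed (-0.56, adjusted p = 0.0653, and -2.94, adjusted p = 0.0525); both were named after their values had been seen. MUC2 stood at 110 ± 10.1 CPM (SD, n = 2 lines) in NTC lines and 89.2 ± 6.59 CPM (SD, n = 3 lines) in guide lines. SPDEF and ATOH1, transcription factors of secretory cells, had values of -0.19 and -0.17, and fell adjusted over the list alone. By guide, the list median was -0.13 for sg1 (camera adjusted p = 0.00699), -0.12 for sg2 (adjusted p = 0.00395) and -0.02 for sg3 (adjusted p = 0.745); whether the guides differ was not tested for the list. With an estimated correlation the adjusted p was 0.726 for sg1 and 0.944 for sg2. These markers also moved with the letter: MUC2 was 0.65 and FCGBP 0.90 higher on the log2 scale in B than in A. In A libraries alone the list median was -0.10 and in B libraries alone -0.11, both past the camera threshold, with adjusted p of 0.873 and 0.952 with an estimated correlation. The camera call ended when line NTC2 (median -0.08), line sg2 (-0.10), or one of the libraries NTC1 B (-0.06), NTC2 B (-0.06) or sg3 A (-0.08) was left out. The values with a single library left out again mix letter with arm.

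**Figure D3:**
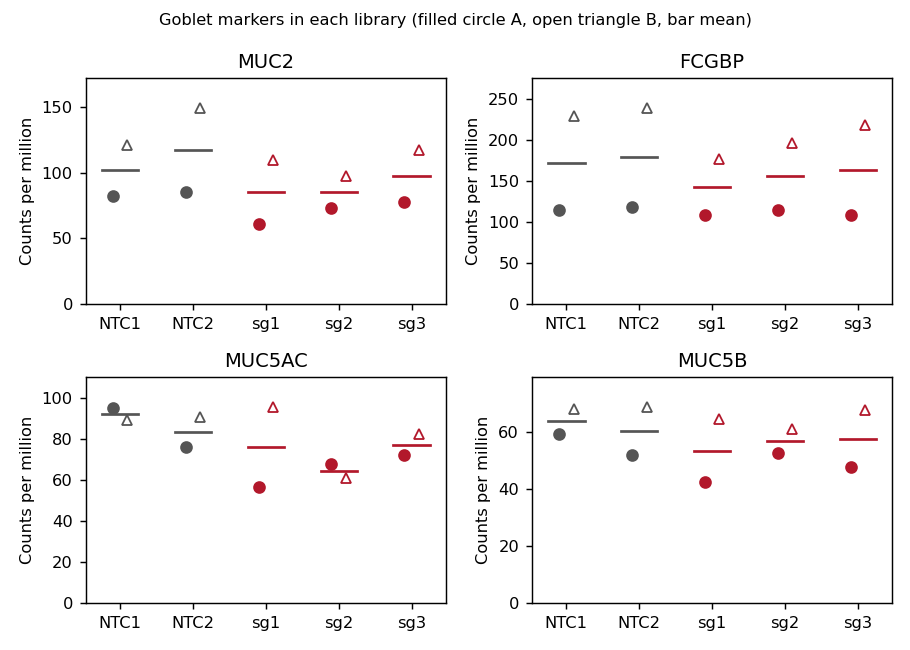
MUC2, FCGBP, MUC5AC and MUC5B in CPM (vertical axes) in each library of the 5 lines (horizontal axes), with filled circles for A, open triangles for B and bars for the mean of a line. MUC2 ranges from 61.3 CPM in sg1 A to 149 CPM in NTC2 B, and for MUC2 and FCGBP each line's B library lies above its A library.

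Genes of innate immunity and inflammation did not pass the test over all genes. The median log2 fold change was 0.03 over 38 interferon-stimulated genes, 0.03 over 19 RNA and DNA sensors, 0.00 over 19 antigen presentation genes and 0.04 over 29 TNF and NF-kB targets. Abundant interferon-stimulated genes included LGALS3BP (0.05, SE 0.03) and IFITM3 (0.04, SE 0.03). The double-stranded RNA deaminase ADAR had a log2 fold change of 0.01 (SE 0.03), the sensor adaptor MAVS 0.06 (SE 0.03) and the kinase EIF2AK2 0.02 (SE 0.03). Adjusted over the list alone, OAS3 was higher by 0.12 (SE 0.03, adjusted p = 0.0395). The camera adjusted p ranged from 0.209 for the TNF and NF-kB targets to 0.651 for the interferon-stimulated and antigen presentation genes. In fry's test for changes in either direction, the TNF and NF-kB targets had an adjusted p of 0.00971, with 18 members positive and 11 negative. Over the list alone 0 of 29 passed the edgeR test, with 4 at an unadjusted p under 0.05 and 0 called by DESeq2. The 32 immediate early genes had a median of 0.01, with MYC at 0.01 (SE 0.03) and MCL1 at -0.01 (SE 0.03).

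Genes of RNA metabolism, translation and growth lay close to the NTC level. The 34 RNA decay genes had a median log2 fold change of -0.02, with the poly(A)-binding protein gene PABPC1 at 0.01 (SE 0.03) and the deadenylase scaffold CNOT1 at -0.02 (SE 0.03). The 77 cytosolic ribosomal protein genes had a median of -0.02, with RPS2 at -0.02 and RPLP0 at -0.04. The list median ran from -0.07 without NTC2 B to 0.03 without NTC2 A, both past camera, and was -0.07 in A libraries alone and 0.04 in B libraries alone, both past camera as well. With a single library left out the letters are unbalanced, and ribosomal protein genes differed by letter. The 29 rRNA synthesis genes had a median of -0.01, with NPM1 at -0.07 (SE 0.02) and NCL at 0.04 (SE 0.02). The medians were 0.00 for 30 S phase genes, 0.01 for 30 G2/M genes and 0.03 for 10 histone genes. The mitochondrial-genome mRNAs were negative in 13 of 13 members, with a median of -0.08 (camera adjusted p = 0.0600). This value depended on single lines and libraries: the median was -0.20 without line NTC1 (adjusted p = 1.50e-08) and turned to 0.03 without line NTC2 (adjusted p = 0.524). The list also passed without line sg1 (-0.12), NTC1 A (-0.13), sg1 B (-0.16) or sg2 B (-0.12), and the median was 0.00 without sg1 A, -0.03 without sg2 A and -0.04 without NTC1 B. Leaving out a single library unbalances the letters here as well. It was -0.21 in A libraries alone, past camera, and 0.02 in B libraries alone, which was not. With the letter as a block (-0.09, adjusted p = 0.0368) and at a mean of 5 CPM or more (-0.08, adjusted p = 0.0106) the list passed, and with an estimated correlation its adjusted p was 0.943. MT-CO1 stood at -0.08 (SE 0.05), and adjusted over the list alone MT-ND3 fell, at -0.21 (SE 0.05). The 32 nuclear oxidative phosphorylation genes had a median of -0.01.

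Stress, metabolic and epithelial programmes gave values in the same range. The medians were -0.01 for 30 p53 targets, 0.00 for 30 genes of the unfolded protein and integrated stress responses (camera direction down, adjusted p = 0.792), 0.00 for 17 heat shock genes, -0.01 for 24 NRF2 and oxidative stress genes and -0.01 for 27 hypoxia and glycolysis genes. CDKN1A, a cell cycle inhibitor induced by p53, had a log2 fold change of 0.03 (SE 0.03), the chaperone gene HSPA5 one of -0.03 (SE 0.02), and GAPDH 0.00 (SE 0.03). The 30 cholesterol and fatty acid synthesis genes had a median of 0.02, with FASN at 0.09 (SE 0.04) and SCD at 0.13 (SE 0.07). The 21 genes of the PXR and AHR response had a median of 0.00. The 26 Wnt targets had a median of -0.02. Adjusted over the list alone, the Wnt targets SMOC2 (-0.20), PROX1 (-0.23) and APCDD1 (-0.27) fell and DKK1 (0.44) rose. The medians were 0.02 for 30 epithelial adhesion and keratin genes, 0.02 for 20 enterocyte genes, 0.09 for 7 enteroendocrine genes, -0.02 for 17 mesenchymal genes and 0.03 for 19 YAP and TAZ targets. Adjusted over the list alone, the integrin gene ITGB4 rose (0.14), CRIM1 (0.10) and MYOF (0.15) rose, and DLC1 fell (-0.14). Markers of fibroblasts, endothelium, leukocytes and an embryonic kidney line had medians of 0.10 (8 genes), -0.06 (5 genes), 0.04 (6 genes) and -0.02 (6 genes).

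**Figure D4:**
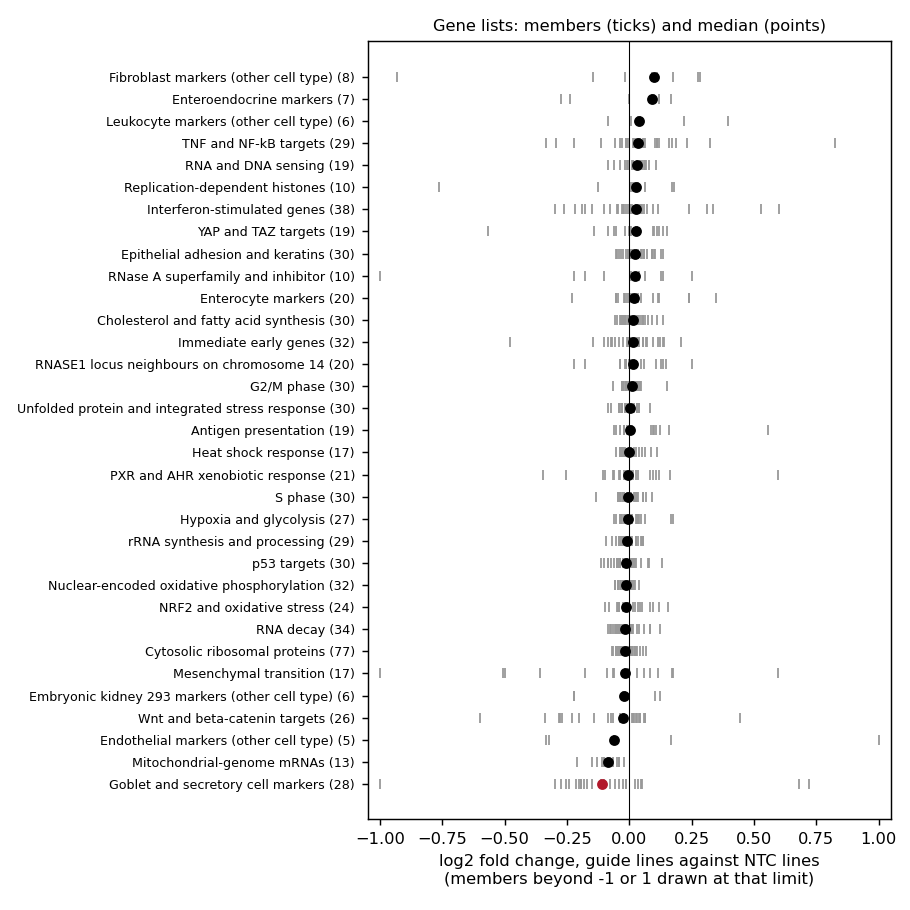
Log2 fold change of guide lines against NTC lines (horizontal axis) for the measured members (ticks) and the median (points) of each of 33 gene lists (vertical axis, number of measured members in brackets). The goblet and secretory markers, in red, are the list past the camera threshold, with a median of -0.11.

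Around RNASE1, the gene nearest to a call was AL163636.2, which overlaps other ribonuclease genes. In the 500 kb on either side, a window outside the plan, 23 other genes were tested with edgeR and 0 passed. Of them 6 had an unadjusted p under 0.05, and 18 had an interval within 1.5-fold. Adjusted over these genes alone, 1 passed at an adjusted p of 0.00974, AL163636.2 (chromosome 14 from 20684587 to 20700576, plus strand), which was higher by 1.23 (SE 0.26) and was named after its value had been seen. Over all genes it passed with DESeq2 (adjusted p = 0.00446), with no filter, with line means and the letter as a block (1.16, adjusted p = 0.0454) and without line sg2 (1.49, adjusted p = 0.0150), but not with the GC correction added to that block (1.18, adjusted p = 0.0525). Its annotation overlaps the ribonuclease genes ANG, at -0.18 (SE 0.11), and RNASE4, at -0.22 (SE 0.07), on the same strand. RNASE4 passed as lower over the RNase A list alone (edgeR adjusted p = 0.0423), a family that holds the target RNASE1 itself. It did not pass over the listed locus neighbours (0.118) or over the window with RNASE1 included (0.0565). The ribonuclease inhibitor gene RNH1 had a log2 fold change of 0.04 (SE 0.03), at 160 ± 2.84 CPM (SD, n = 2 lines) and 165 ± 3.77 CPM (SD, n = 3 lines). The RNase A list held 10 measured genes with a median of 0.02, while camera gave its direction as down (adjusted p = 0.601), with RNASE1 among its members. The median of 20 listed locus neighbours was 0.01.

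Each guide line on its own differed from the NTC lines in RNASE1. The log2 fold change was -4.10 (SE 0.21, edgeR adjusted p = 1.23e-04) for sg1, -2.53 (SE 0.18, adjusted p = 0.00226) for sg2 and -3.67 (SE 0.20, adjusted p = 2.15e-04) for sg3, which left 5.84%, 17.3% and 7.88% of the NTC level. RNASE1 was the 1 gene of 16411 past the threshold in each of the 3 comparisons, and hence the 1 gene shared by all guides. In 20 simulations of unchanged lines, with the controls simulated as well, 0 genes were shared. The product of independent lists gave 3.71e-09. Both say little, because this fit makes few calls and each list held RNASE1 alone. Against NTC1 alone and against NTC2 alone the shared count was 1 as well. RNASE1 is the target of all 3 guides, so this sharing shows the knockdown and no more. Unadjusted p-values under 0.05 numbered 377 for sg1, 298 for sg2 and 354 for sg3, fewer than uniform p-values would give. This fit leaves the letter, by which 29.6% of genes differed, in its spread. Few calls in it therefore do not show that other genes were unchanged. With the letter as a block, 4 genes passed for sg1 (RNASE1, OLFM4, TBX2 and H19), 2 for sg2 (RNASE1 and PALM) and 6 for sg3 (RNASE1, H19, CTAG2, AL163636.2, SULT1A3 and AP000547.3). OLFM4 was at -0.88 (SE 0.13, adjusted p = 0.0498) in sg1. The imprinted noncoding RNA H19 was at 0.33 (SE 0.04) in sg1 and 0.29 (SE 0.04) in sg3. With a correction for GC content added to the block, RNASE1 alone passed for sg1: OLFM4 stood at -0.85 (SE 0.13, adjusted p = 0.0565), TBX2 went from 0.90 (SE 0.12) to 0.84 (SE 0.12, adjusted p = 0.0565) and H19 stood at 0.29 (SE 0.04, adjusted p = 0.0626). In sg3 H19 then stood at 0.23 (SE 0.04, adjusted p = 0.212), and the other 5 genes passed. Genes beyond RNASE1 in these blocked fits were named after their values had been seen. Without sg2 A, RNASE1 in sg2 stood at -2.45 (SE 0.25, 95% interval -3.03 to -1.88) on 1 library, assumed to vary like those of the other lines. Its adjusted p was then 0.108, which ended its call in sg2 and the shared count while the fold stayed close to that of both libraries.

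The level of RNASE1 differed among the guide lines. RNASE1 was higher in sg2 than in sg1 by 1.57 (SE 0.24, edgeR p adjusted over 3 contrasts = 0.000276) and higher in sg2 than in sg3 by 1.13 (SE 0.23, adjusted p = 0.00103). Between sg3 and sg1 the difference was 0.43 (SE 0.26, adjusted p = 0.135). These 3 contrasts were not among the planned tests, which held the F test over the guides. Adjusted over all genes, 0 genes passed edgeR in each of these contrasts, with RNASE1 at 0.754 for sg2 against sg1. Each guide was in 1 line, so the strength of a guide and a difference between lines cannot be told apart. Over all 16411 genes, 0 passed the edgeR F test of a difference among guides. An unadjusted p under 0.05 was found for 226, fewer than uniform p-values would give, in the fit that leaves the letter in its spread. DESeq2 called 8. The 5 genes with the smallest p were PALM, SULT1A3, RNASE1, GAGE1 and PEG10. PALM, which encodes the membrane protein paralemmin, was at 0.778 ± 0.0377 CPM (SD, n = 2) in sg2 and 0.0242 ± 0.0342 CPM (SD, n = 2) in sg1. The sulfotransferase gene SULT1A3, a near-identical copy of SULT1A4 with uncertain counts, was at 4.13 ± 0.553 CPM in sg3 and 0.685 ± 0.0733 CPM in sg2. GAGE1, a cancer-testis antigen gene of a family of close copies, was at 3.88 ± 0.219 CPM in sg1 and 0.258 ± 0.331 CPM in sg2. PEG10, an imprinted gene, was at 1.66 ± 0.294 CPM in sg3 and 0.556 ± 0.0688 CPM in sg1. With the letter as a block 8 genes passed, which included PALM, SULT1A3, RNASE1 and GAGE1; with the GC correction as well 3 passed, RNASE1, GAGE1 and SULT1A3, and PALM had an adjusted p of 0.0565.

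The NTC lines gave the background for differences between lines. In NTC2 against NTC1, 0 of 16411 genes passed the edgeR test, with 282 at an unadjusted p under 0.05 and 2 called by DESeq2. The 282 are again fewer than uniform p-values would give, in the same fit without the letter. RNASE1 differed by 0.07 (SE 0.17). With the letter as a block 2 genes passed, U2AF1 at -1.12 (SE 0.15) and AC000120.3, both named after their values had been seen. At the level of lists, 4 of 32 passed camera between the NTC lines. All were higher in NTC2: the mitochondrial-genome mRNAs (median 0.23), ribosomal proteins (0.06), oxidative phosphorylation (0.05) and the RNase A list (0.13). With an estimated correlation each had an adjusted p of 0.885. The cholesterol and fatty acid synthesis list was lower in sg1 (median -0.05, camera adjusted p = 0.0223) and higher in sg2 (0.06, adjusted p = 0.0104), with adjusted p of 0.953 and 0.944 with an estimated correlation.

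The fold changes of the guides were correlated with each other across 10756 genes at 5 CPM or more, RNASE1 left out. Pearson's r was 0.382 for sg1 and sg2, 0.489 for sg1 and sg3, and 0.508 for sg2 and sg3; genes are not independent replicates. Simulated unchanged lines that shared simulated controls gave mean r of 0.323, 0.328 and 0.328, with the highest at 0.386, 0.365 and 0.363. The value for sg1 and sg2 thus lay within the simulated range. The covariances were 0.00251, 0.00323 and 0.00326, against simulated values of 0.00165, 0.00169 and 0.00168. The simulations treat genes as independent and hold no difference between lines and no GC trend. Values above their range therefore do not show a response shared by the guides. With the controls split, so that one guide was set against NTC1 and the other against NTC2, r lay between 0.0724 and 0.179 over the 6 arrangements.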

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

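The tests of the GC trend, of AL163636.2, of the splits for the number of genes, and of the GC and letter explanations for the goblet markers were chosen after the results were seen, and the splits for the goblet markers before. Of 40 groups of 4 or 6 libraries tested for a sample far from the others, 1 stood out, where chance gives about 1 in 20: PALM was at 0 CPM in NTC1 A against 0.0219 CPM in the nearest NTC library, a matter of 0 counts against 1 count. RNASE1 differed between guide lines by a test of the difference itself, with sg2 above sg1 by 1.57 and above sg3 by 1.13 on the log2 scale.

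The comparison of arms called 4 genes. With 5 lines there are 10 splits into 3 and 2, too few for a share under 0.05. As many genes were called by 3 of the 10 splits, the real one included, and the most in another split was 8, from NTC1, NTC2 and sg3 against sg1 and sg2.

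The goblet and secretory markers were lower in the guide lines, with a median log2 fold change of -0.11, a call by camera that was lost with fry (adjusted p = 0.662). Removing the GC trend left the median at -0.12 and past the camera threshold (with an estimated correlation the adjusted p was 0.938, and 0.943 before the removal), which argues against that trend as the whole cause. The state that separates A from B is argued against as a whole: over 4724 genes that differ by letter, list members left out, the arm change had a slope of 0.0114 (SE 0.00534) on the letter change, where -0.787 would be needed. That slope pools all genes that differ by letter, so it cannot exclude a part of the letter state. Of the 10 splits of the lines, 3 gave as small a camera p for the list, and the smallest p in another split was 3.60e-09, from NTC1, NTC2 and sg3 against sg1 and sg2; the splits are too few for a share under 0.05. A response to RNASE1 knockdown and a difference between single lines may each account for the lower markers and cannot be told apart here, as sg3, with 7.88% of RNASE1 left, had a median of -0.02.

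Across 9523 genes at 10 CPM or more, the fold change between arms rose with transcript GC content (Spearman's rho 0.500). The slope per 10 percentage points of GC was 0.0118 ± 0.0149 (SD, n = 3 lines) in guide lines and -0.0177 ± 0.00383 (SD, n = 2 lines) in NTC lines, with an exact two-sided permutation p of 0.2 where 0.1 is the smallest the design allows. GC bias of single libraries may account for it: the 2 libraries of a line differed in slope by 0.877 times the difference between the arms on average. That ratio cannot decide, because it sets single libraries against means over several libraries, which vary less. RNASE1 cleaves RNA after pyrimidines, with UA dinucleotides among its preferred sites, so a loss of cleavage could raise UA-rich transcripts. The partial correlation of the arm change with UA density given GC was -0.0575, opposite in sign to that prediction, but it was above 0 in 1 of 6 pairs of a guide line and an NTC line (range -0.126 to 0.0576), a criterion set after the value was seen, so the question stays open.

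AL163636.2 was higher in the guide lines by 1.23 on the log2 scale. Reads divided differently among AL163636.2, ANG and RNASE4 are a candidate explanation: summed, the 3 genes differed by -0.0557 (SE 0.07), at 15.6 ± 1.59 CPM (SD, n = 2 lines) and 14.96 ± 0.867 CPM (SD, n = 3 lines). More transcription across these genes is argued against, since the upper 95% limit of the sum was 0.0883 and the added AL163636.2 counts alone would have raised it by 0.12. That bound was set after the value had been seen, in place of one that had not been computed. A shift between transcript forms in these cells was not tested.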

How the results depend on the processing

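The GC correction, the newer quasi-likelihood estimate, line means with a block and the added list settings were chosen after seeing the data. RNASE1 stayed lower and past the threshold in 28 of 28 alternatives (log2 fold change -3.87 to -2.99). SOD3 passed in 11 of 28 (0.14 to 0.38), TNS4 in 11 of 28 (0.15 to 0.28) and AC010487.3 in 18 of 27. FCGBP ranged from -0.43 to 0.0608 with a library left out, turning to 0.05 without NTC1 B and to 0.0608 without NTC2 B; leaving out 1 library unbalances the letters. The 4 genes of the comparison of arms became 55 with DESeq2, 238 with no filter, 1 with an arm term, 2 with the replicate block, 1 with line means, 9 with line means and the replicate block (3 with the GC correction as well), 1 with voom and 11 with A libraries alone, and 1 to 29 with a library or line left out (29 without line NTC1). With DESeq2 the counts for sg1, sg2, sg3, NTC2 against NTC1, all 3 guides and the difference among guides were 6, 4, 4, 2, 2 and 8, and with no filter 69, 95, 86, 57, 12 and 141. With the replicate block sg1 had 4, sg2 2, sg3 6, NTC2 against NTC1 2 and the difference among guides 8; with the GC correction as well, sg1 had 1, sg2 3, sg3 5, NTC2 against NTC1 2 and the difference among guides 3. The newer estimate gave 2 for sg2 and 1 for the difference among guides. With a library left out the counts ran from 1 to 2 for sg1, 0 to 2 for sg2, 1 to 1 for sg3, 0 to 1 for NTC2 against NTC1, 0 to 1 for all 3 guides and 0 to 2 for the difference among guides. The 1 gene list past camera became 0 with an estimated correlation, 0 with fry's directional test, 3 with the replicate block, 2 at a mean of 5 CPM or more, 3 with the GC correction, 5 with A libraries alone, 2 with B libraries alone and 0 to 4 with a library or line left out. Genes with no filter include 53 under 1 CPM among the 238. The causes of these changes were not tested.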

Other observations

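The tests by letter in this part were chosen after the data were seen. The first principal component of the libraries, with 18.2% of the variance, separated letters A and B. With the line as a block, 4850 of 16411 genes (29.6%) differed between B and A in the edgeR test, 2392 higher and 2458 lower in B, and 234 of them by over 1.5-fold. In B, the intestinal stem cell marker OLFM4 was higher by 1.06 on the log2 scale (SE 0.09), the mucus protein FCGBP by 0.90 (SE 0.04) and the mucin MUC2 by 0.65 (SE 0.05). The lower genes in B included the trefoil factor TFF1 at -0.76 (SE 0.05), the Wnt inhibitor DKK1 at -1.03 (SE 0.08), the cytokine IL33 at -0.76 (SE 0.06) and the hypoxia-induced carbonic anhydrase CA9 at -0.58 (SE 0.04). These genes were chosen after their values were seen.

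Ribosomal protein genes were lower in B in 57 of 77 members past the gene test and higher in 0 (list median -0.13). Of 27 hypoxia and glycolysis genes 13 were lower and 3 higher (median -0.09), and of 32 oxidative phosphorylation genes 19 were lower and 4 higher (-0.09). Of 30 S phase genes 14 were higher and 2 lower (0.07), of 26 Wnt targets 14 were higher and 3 lower (0.11), and of 29 rRNA synthesis genes 12 were higher and 1 lower (0.06). Of 27 goblet and secretory markers 13 were higher and 3 lower (0.14). These 7 lists and the heat shock list passed camera and fry, and the mitochondrial-genome mRNAs passed camera but not fry (adjusted p = 0.193); with an estimated correlation the adjusted p was 0.599 for the S phase, hypoxia, rRNA synthesis, Wnt, goblet and heat shock lists, 0.606 for ribosomal proteins, 0.657 for oxidative phosphorylation and 0.759 for the mitochondrial-genome mRNAs. The labels do not say what the letters stand for.

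DESeq2 called 55 genes between the arms, 52 of them at 1 CPM or more. Its fit held no correction for GC content, with which the fold change between arms rose (Spearman's rho 0.500). Beside the 4 genes of edgeR, the smallest adjusted p among higher genes were those of IL33 (0.34, adjusted p = 0.000353), EVPL (0.27) and MALL (0.25), and among lower genes those of MATR3 (-0.29), PRSS2 (-0.33) and CDK6 (-0.12). These were chosen after their values were seen, and none passed edgeR in the comparison of arms with counts summed per line. PRSS2 passed edgeR with line means and the letter as a block (-0.33, adjusted p = 0.0454), but not with the GC correction as well (-0.35, adjusted p = 0.0525).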
